A study of Mus musculus with 9 samples.

How the data were processed

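The series measured gene expression in 3 populations of luminal epithelial cells sorted by flow cytometry from adult mouse mammary glands, with 3 libraries per population. Lineage-positive cells had been excluded in the sort, and the remaining cells were separated by the surface protein CD14 and by a YFP reporter driven by PR-cre. The populations are named here as the labels abbreviate them: HR-negative LP (CD14 positive, YFP negative), HR-positive LP (CD14 positive, YFP positive) and ML (CD14 negative). The labels of the ML libraries call them YFP positive, whereas the series' own design text calls them YFP negative. The sample labels were followed, and the level of the gene Pgr, which encodes the progesterone receptor, is given for each population.

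Total RNA had been extracted with a miRNeasy kit and treated with DNase, and libraries had been prepared from at least 50 ng with the TruSeq RNA Library Prep Kit v2, per the labels' protocols. This kit does not mark the strand, so reads from a gene and an antisense partner cannot be told apart. The authors deposited raw counts of reads per gene, which the submitters' processing notes tie to featureCounts and the genome build mm10. The aligner, the gene annotation and the treatment of reads with several matches were not given in the sources used here. Values in the table of the whole series and in the file of each sample were the same, with 0 cells differing, so each library was read once. Gene IDs were NCBI numbers. Of the 27179 genes, 25275 (93.0%) were matched to a symbol and a position in the RefSeq annotation of the same build, and 1904 were left without a name but kept in the tests. The unmatched IDs held between 0.955% and 1.67% of the counts of a library. In all, 7254 genes had no count in any library.

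Genes were filtered with edgeR's filterByExpr by group, which left 15910 tested genes, and libraries were scaled by TMM factors. Each pair of populations was compared with edgeR's quasi-likelihood F test (glmQLFit and glmQLFTest) on the counts of all 9 libraries, with no covariate. P-values were adjusted by Benjamini-Hochberg over the tested genes and called at 0.05. Log2 fold changes are given with their standard error (SE), and levels as TMM-scaled CPM (counts relative to a fixed library total), computed from the deposited counts, with the SD over 3 libraries. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15 and matplotlib 3.10.9. The position of HR-positive LP between HR-negative LP (0) and ML (1) was the median over genes called between these ends with an absolute log2 fold change over 1, on log2 CPM with a prior count of 2. A set of 27 gene lists with 450 genes, drawn from general knowledge of mammary cells, was tested with limma's camera on voom values at a preset correlation of 0.01. These 81 tests were adjusted together by Benjamini-Hochberg. In the files 449 of the list genes were found and 415 were tested. The lists, the tests, the rule for naming genes and the alternatives were set before the data were examined, except for alternatives said to have been added later.

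Genes are named in each comparison by a fixed rule. It took the 10 largest positive and 10 largest negative log2 fold changes among genes with an adjusted p below 0.05, an absolute log2 fold change over 1, a mean log2 CPM over 3 and no overlap of CPM between both groups. Predicted genes, clones, pseudogenes and unnamed IDs were left out. From each list, up to 4 members with the smallest p were added. Cd14, Pgr, Esr1, Kit, Elf5 and Foxa1 were always included. For genes apart from both other populations, the 10 highest and 10 lowest by the smaller absolute log2 fold change were taken under the same filters.

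Depth ranged from 27219103 to 108119756 counts per library, so counting error was small for genes above a few CPM and the spread between libraries set the precision. The procedure was tested on simulated data with each gene's mean over all 9 libraries, the real library sizes and dispersions, and 200 genes raised in HR-positive LP. HR-negative LP and ML were equal in it, unlike in the real data, where 7089 genes were called between them. Recovery in the real data may therefore differ. In the simulated comparison of HR-positive LP with HR-negative LP over 15910 genes, 48 of 100 genes raised 2-fold and 81 of 100 raised 4-fold were called, with 13 false calls. In the simulated comparison of ML with HR-positive LP the counts were 32 and 80, with 5 false calls. Genes higher than in both others were recovered for 31 of 100 at 2-fold and 78 of 100 at 4-fold, with 0 false calls.

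The labels number the libraries of each population 1 to 3 without saying whether a number marks a shared animal or day. Deviations of same-numbered HR-positive LP and ML libraries from their group means had correlations across genes of 0.183, 0.121 and 0.189. All were over 0.1, so the numbers may pair these libraries, from the data alone. The main tests did not use this pairing. With the number as a block, 71 genes were higher and 1253 lower in ML than in HR-positive LP, against 15 and 1066 without it. The correlations were 0.133, 0.0388 and 0.146 between HR-negative LP and HR-positive LP. Between HR-negative LP and ML they were 0.0526, 0.0254 and 0.0849. Neither set was all over 0.1. Yet every same-numbered correlation was above the highest between differently numbered libraries (0.0192), so the number may mark something shared by all 3 populations. Deviations from a mean of 3 libraries cancel within a group, so positive same-numbered correlations force the others down. Both sets are thus not independent, and their contrast overstates the evidence. No source says that the libraries came from separate animals, so p-values measure the spread between these libraries, which may be partly technical. No pair of libraries was a duplicate, since a chi-square per degree of freedom of 65.6 to 220.3 separated the counts of replicates.

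Alternatives were a replicate block, DESeq2, voom, DESeq2's size factors, upper quartile factors, no count filter, a filter of CPM over 1 in 3 libraries, a fit of only the groups compared, leaving out each library, and a threshold on fold change. For lists they were an estimated correlation, the rotation test fry, the block, the filter of CPM over 1 and leaving out each library. Thinning all libraries to the smallest total and scaling by library totals alone were chosen after seeing the data. Scaling by totals alone put the median log2 fold change of all genes at 0.12 for HR-positive LP against HR-negative LP and 0.19 for ML against HR-negative LP, where TMM gave 0.01 and 0.03. The share of 50-base windows of a gene's transcripts that also occur in another gene was computed from GENCODE transcripts of the same build, to mark genes whose reads could be split. Among named genes it was over 10% for Hspa1a (66.3%), Hspa1b (62.3%), Trf (59.4%), Pgk1 (53.9%), Pkm (25.8%), Gapdh (25.1%), Pcna (19.1%), Ly6a (19.0%), Cebpb (18.1%), Dpep2 (16.0%), Paqr6 (12.9%) and Bglap3 (11.5%), whose levels are uncertain. Over protein-coding transcripts alone it was also over 10% for Cox5a (32.0%) and Notch1 (13.3%), which are uncertain too, and Cdcp3, Il33, Hp and Rn7sk were not checked. The values of 1 list member are not reported here.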

Results

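Gene expression was measured in 9 libraries from 3 sorted populations of adult mouse mammary luminal cells, each with 3 libraries. The populations differed in CD14, a surface receptor that takes part in the recognition of bacterial products, and in a YFP reporter driven by PR-cre. HR-negative LP libraries held 50650478, 108119756 and 29843142 counts, HR-positive LP libraries 99206739, 64779135 and 92179701, and ML libraries 27219103, 46622681 and 40460017. Between 15239 and 17735 genes were detected per library. The first principal component held 61.4% of the variance and the second 10.1%. On the second, HR-negative LP replicate 3 stood apart from replicates 1 and 2, at -91.6 against 15.9 and 39.5. Without it 2651 genes were higher and 1975 lower in HR-positive LP than in HR-negative LP, 36 and 1137 in ML than in HR-positive LP, and 3558 and 3391 in ML than in HR-negative LP, where all libraries gave 2731 and 2033, 15 and 1066, and 3700 and 3389. The design asks how the CD14-positive cells with and without the reporter differ from each other and from the CD14-negative population.

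Levels of the gate genes were looked at first. Cd14 (gene ID 12475, chromosome 18, 36725064 to 36726815, mm10) stood at 1114 ± 103 CPM in HR-negative LP, 324 ± 35.2 CPM in HR-positive LP and 24.7 ± 6.04 CPM in ML (SD, n = 3). Pgr (gene ID 18667, chromosome 9, 8898900 to 8968611), which encodes the progesterone receptor, stood at 9.42 ± 5.54, 279 ± 65.8 and 435 ± 144 CPM. Esr1 (chromosome 10, 4611989 to 5005633), the estrogen receptor gene, was at 15.1 ± 5.83, 123 ± 8.83 and 162 ± 4.13 CPM. Foxa1 (chromosome 12, 57540628 to 57548029), a pioneer factor of hormone receptor binding, was at 54.7 ± 15.6, 354 ± 62.6 and 477 ± 110 CPM. Kit (chromosome 5, 75574987 to 75656722), a receptor tyrosine kinase of progenitor cells, and Elf5 (chromosome 2, 103412098 to 103450989), a regulator of the alveolar lineage, ran the other way. Kit was at 1537 ± 227, 515 ± 47.7 and 7.46 ± 4.66 CPM, and Elf5 at 434 ± 111, 151 ± 8.67 and 36.0 ± 17.5 CPM. In all 6 genes the mean of HR-positive LP lay between those of both other populations.

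**Figure D1:**
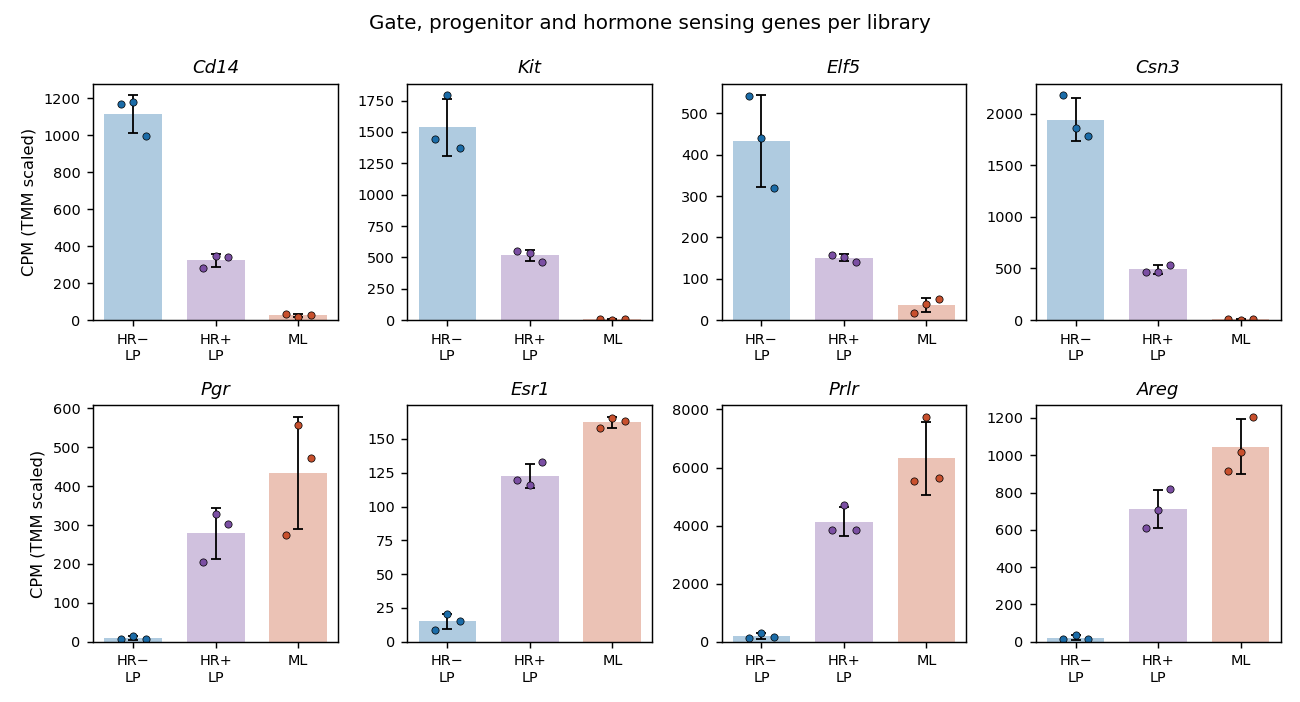
CPM (y axis, TMM scaled, linear, from 0) of 8 genes in HR-negative LP, HR-positive LP and ML; bars are means of 3 libraries, error bars SD and points single libraries. Cd14 falls from 1114 to 324 and 24.7 CPM across the populations while Esr1 stands at 15.1, 123 and 162 CPM.

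HR-positive LP carried a hormone sensing programme that HR-negative LP held at lower levels. Of 18 tested hormone sensing genes, 15 rose and 0 fell in HR-positive LP (16 rose adjusted over the list alone). Prlr, the prolactin receptor gene, rose from 198 ± 95.1 to 4131 ± 494 CPM, a log2 fold change of 4.38 (SE 0.33, adjusted p = 7.84e-06). Areg, which encodes the EGF receptor ligand amphiregulin, rose from 21.9 ± 13.0 to 712 ± 104 CPM, and Ly6a, which encodes the surface antigen Sca-1, from 15.5 ± 8.62 to 629 ± 124 CPM. Esr1 was higher by a log2 fold change of 3.02 (SE 0.25, adjusted p = 1.28e-05) and Foxa1 by 2.69 (SE 0.25, adjusted p = 2.82e-05). The gate gene Pgr, tied to the sorting reporter and not a member of that list, was higher by 4.87 (SE 0.43, adjusted p = 1.97e-05). The list as a whole moved up with a camera adjusted p of 3.76e-11, and with adjusted p = 0.139 with an estimated correlation.

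Genes of the alveolar lineage were lower in HR-positive LP than in HR-negative LP. Of 16 alveolar progenitor genes 14 fell and 0 rose, by all-gene adjustment and adjusted over the list alone (camera adjusted p = 1.23e-08, and adjusted p = 0.029 with an estimated correlation). Mfge8, which encodes a milk fat globule protein, fell from 4930 ± 584 to 1575 ± 153 CPM (log2 fold change -1.65, SE 0.29), and Wfdc18 from 768 ± 165 to 218 ± 30.5 CPM. Elf5 fell by 1.53 on the log2 scale (SE 0.33, adjusted p = 0.00524) and Kit fell by 1.58 (SE 0.42, adjusted p = 0.0161). The gate gene Cd14, not a member of that list, fell by 1.78 (SE 0.19, adjusted p = 5.87e-05). The call for Kit was lost without HR-positive LP replicate 2 (adjusted p = 0.0563) or replicate 3 (adjusted p = 0.0561). Among 10 milk synthesis genes 6 fell by either adjustment, including the casein gene Csn3, from 1943 ± 210 to 490 ± 40.0 CPM, and Xdh, from 395 ± 113 to 124 ± 16.1 CPM. The milk synthesis list had a camera adjusted p of 1e-04, and adjusted p = 0.0953 with an estimated correlation.

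Transcription factors and signalling genes moved in both directions between the CD14-positive populations. Of 19 lineage transcription factors 8 fell and 4 rose by either adjustment. Nfib fell from 762 ± 20.8 to 338 ± 8.68 CPM, Cebpb from 1940 ± 107 to 613 ± 122 CPM and Tfap2c from 153 ± 18.5 to 52.5 ± 4.43 CPM. The transcription factor list had a camera adjusted p of 0.00879, and adjusted p = 0.104 with an estimated correlation. Of 16 Notch pathway genes 5 fell and 2 rose (7 and 2 adjusted over the list alone). The Notch ligand gene Jag1 rose from 5.84 ± 2.62 to 74.4 ± 1.63 CPM and the receptor gene Notch1 fell from 357 ± 65.4 to 197 ± 28.4 CPM. The Notch list had a camera adjusted p of 0.0255, lost without HR-negative LP replicate 2 (adjusted p = 0.0823), and adjusted p = 0.145 with an estimated correlation. Of 21 Wnt pathway genes 9 fell and 2 rose by either adjustment, with camera adjusted p = 0.0166, and adjusted p = 0.111 with an estimated correlation. The Wnt ligand genes Wnt7b and Wnt11 rose, to 103 ± 14.4 and 13.2 ± 3.42 CPM, while the receptor gene Fzd1 fell from 43.6 ± 6.50 to 16.4 ± 1.96 CPM. Of 9 EGF family genes 2 rose and 2 fell (4 and 3 adjusted over the list alone, camera adjusted p = 0.907). Egfr fell from 141 ± 47.5 to 50.2 ± 4.34 CPM and Erbb2 rose from 92.0 ± 7.4 to 159 ± 19.2 CPM.

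Innate defence genes and immediate early genes fell in part in HR-positive LP. Of 12 innate defence genes 7 fell and 0 rose by either adjustment (camera adjusted p = 0.000556, and adjusted p = 0.111 with an estimated correlation). Among them, Tlr4 fell from 60.1 ± 15.5 to 27.6 ± 1.18 CPM, and Lbp from 28.2 ± 6.26 to 7.02 ± 0.221 CPM. Of 19 immediate early and heat shock genes 11 fell and 1 rose by either adjustment (camera adjusted p = 0.00564, adjusted p = 0.576 with an estimated correlation, and 0.0542 with fry). Ier3 fell from 971 ± 174 to 362 ± 11.9 CPM and Nr4a1 from 1371 ± 236 to 615 ± 55.7 CPM, while the heat shock genes Hspa1a, Hspa1b, Hsph1 and Dnajb1 were not called (log2 fold changes 0.33, 0.45, -0.17 and -0.11, the first and second uncertain because of shared sequence). Socs3, a feedback inhibitor of cytokine signalling, rose from 163 ± 37.2 to 835 ± 126 CPM. These immediate early and heat shock genes, which respond to tissue dissociation, held 5.70 ± 1.37% of the counts in HR-negative LP, 4.24 ± 0.471% in HR-positive LP and 2.94 ± 0.532% in ML. The inflammatory cytokine and NF-kB list had 6 members lower and 1 higher of 18 (7 and 1 adjusted over the list alone, camera adjusted p = 0.129), with Nfkb1 down from 355 ± 70.8 to 198 ± 30.8 CPM. Without HR-negative LP replicate 1 or HR-positive LP replicate 3 that list was called (adjusted p = 0.0421 and 0.0437). In the interferon list 5 of 19 genes rose and 2 fell by either adjustment (camera adjusted p = 0.907), with Stat2 up from 31.3 ± 5.95 to 79.8 ± 3.85 CPM. Of 7 MHC class II genes 2 rose and 1 fell (2 and 2 adjusted over the list alone, camera adjusted p = 0.994), and the median member was at 2.09 CPM in HR-negative LP and 0.975 CPM in HR-positive LP.

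Of 53 oxidative phosphorylation genes 16 rose in HR-positive LP, 0 fell and 37 were not called, by either adjustment (camera adjusted p = 0.00222, adjusted p = 0.711 with an estimated correlation, and 0.0737 with fry). Ndufa7 rose from 48.0 ± 14.4 to 95.9 ± 5.17 CPM and Cox5a from 49.6 ± 6.13 to 73.3 ± 2.34 CPM. The median of the list was 0.30 on the log2 scale. Of 28 cell cycle genes 1 rose and 2 fell (1 and 1 adjusted over the list alone, camera adjusted p = 0.375), with Pcna down from 130 ± 6.43 to 65.4 ± 2.73 CPM and the mitotic kinase gene Aurka up from 3.61 ± 1.89 to 27.4 ± 1.85 CPM. Of 23 DNA double strand break repair genes 0 were called by edgeR, by either adjustment (2 at an unadjusted p below 0.05, and 1 each by DESeq2 and limma voom, camera adjusted p = 0.375).

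Markers of other cell types had low median levels in all 3 populations, with higher single genes in the basal, fibroblast and endothelial lists. Pan-luminal genes had a median of 1040, 1300 and 1330 CPM in HR-negative LP, HR-positive LP and ML. Median levels were 4.0, 3.15 and 2.24 CPM for basal genes, 0.349, 0.270 and 0.371 CPM for immune genes, and 0.842, 0.611 and 0.811 CPM for endothelial genes. They were 6.48, 3.23 and 3.97 CPM for fibroblast genes, 3.87, 1.42 and 0.901 CPM for adipocyte genes, and 0.239, 1.80 and 2.11 CPM for erythrocyte genes. In HR-positive LP against HR-negative LP, 2 pan-luminal genes rose and 4 fell of 10 by either adjustment (camera adjusted p = 0.497), with Krt7 up from 168 ± 46.9 to 999 ± 247 CPM and Epcam down from 3514 ± 230 to 1884 ± 285 CPM. Of 14 basal genes 4 fell by either adjustment (camera adjusted p = 0.0719, and 0.0421 without HR-negative LP replicate 1 and 0.0463 without HR-positive LP replicate 2, 0.0318 with the filter of CPM over 1 and 0.0118 with fry), among them Lamb3, from 81.8 ± 3.96 to 32.5 ± 2.03 CPM. Among 10 fibroblast genes, the collagen genes Col1a2 and Col3a1 fell from 20.7 ± 6.99 to 2.93 ± 1.29 CPM and from 38.7 ± 11.8 to 5.82 ± 3.90 CPM. In the opposite direction, Dcn and Col6a3 rose from 8.94 ± 2.14 to 128 ± 109 CPM and from 4.02 ± 2.93 to 73.6 ± 41.4 CPM. That list had 7 members lower and 2 higher by either adjustment (camera adjusted p = 0.0196, and adjusted p = 0.402 with an estimated correlation). Vwf, an endothelial and platelet protein gene, rose from 2.92 ± 2.17 to 46.4 ± 13.0 CPM and was 1 of 2 endothelial genes that rose of 10, by either adjustment (camera adjusted p = 0.907). Immune genes gave 1 higher and 1 lower of 7 by either adjustment (camera adjusted p = 0.771). Adipocyte genes gave 1 lower of 3 (2 adjusted over the list alone, camera adjusted p = 0.129, and 0.0283 with fry) and erythrocyte genes 2 higher of 4 by either adjustment (camera adjusted p = 0.375). The median and mean log2 fold change differed in sign for immune genes (-1.06 and 0.24) and endothelial genes (-0.56 and 0.06), as they did for inflammatory genes (-0.42 and 0.09).

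Across all genes, 2731 were higher and 2033 lower in HR-positive LP than in HR-negative LP. The largest rises were those of Gcnt4, a glycosyltransferase gene, from 0.299 ± 0.314 to 40.7 ± 9.0 CPM (log2 fold change 7.56, SE 0.63, adjusted p = 1.37e-05), Cdcp3 (6.99), Dmbt1 (6.31), which encodes a secreted mucosal scavenger receptor, and Syt7 (6.30), a calcium sensor of vesicle release. Krt78, Trpc6, Muc13, Dpep2, Fgg and Aoc1 followed, and the call for Aoc1 was lost with limma voom (adjusted p = 0.131). The largest falls were smaller, from -2.73 for Col3a1 (SE 0.48, adjusted p = 0.00161) through -2.14 for Col9a3 and Chil1 to -1.96 for Cck, with Aqp1, Cst3, Ncald, Ptx3, Csn3 and Bglap3 between them. In each of these genes all 3 libraries of one population lay above all 3 of the other, because the naming rule required it. With scaling by library totals alone, chosen after seeing the data, 3182 genes were higher and 1535 lower. The count of lower genes was 1329 without HR-positive LP replicate 1 and 1211 without replicate 2.

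Of the 1081 genes that differed between ML and HR-positive LP, the YFP-positive populations by the sample labels, 1066 were lower in ML. Rises were small on the log2 scale. Even genes over 64-fold higher in ML than in HR-negative LP had a median of 0.62 between ML and HR-positive LP. In the simulated data 32 of 100 differences of 2-fold were called in this comparison. The counts therefore do not show that ML differed by loss alone. Kit fell by 6.12 on the log2 scale (SE 0.52, adjusted p = 1.45e-05), Cd14 by 3.71 (SE 0.20, adjusted p = 9.04e-07) and Elf5 by 2.06 (SE 0.33, adjusted p = 0.00208). Of 16 alveolar progenitor genes 12 fell (14 adjusted over the list alone, camera adjusted p = 6.27e-20, and adjusted p = 0.02 with an estimated correlation). Sox10 fell from 131 ± 23.6 to 2.97 ± 1.78 CPM, Mfge8 from 1575 ± 153 to 121 ± 61.2 CPM and Trf, the transferrin gene, from 795 ± 75.2 to 10.8 ± 7.83 CPM. Milk synthesis genes fell in 6 of 10 (8 adjusted over the list alone, camera adjusted p = 2.52e-10, and adjusted p = 0.0222 with an estimated correlation), with Csn3 at 8.17 ± 4.08 CPM in ML and Btn1a1 down from 212 ± 25.4 to 3.08 ± 2.13 CPM. For Trf, 59.4% of 50-base windows also occur in another annotated gene, so its level is uncertain.

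No single hormone sensing gene passed the test between ML and HR-positive LP. Of 18 tested genes 0 were called by edgeR, by either adjustment (0 at an unadjusted p below 0.05, and 0 by DESeq2 and limma voom), while the list moved up by a median of 0.41 on the log2 scale (camera adjusted p = 0.000391, adjusted p = 0.507 with an estimated correlation, and 0.213 with fry). The gate gene Pgr, not a member of that list, differed by 0.64 (SE 0.37, adjusted p = 0.564). Esr1 differed by 0.40 (SE 0.23, adjusted p = 0.567), Foxa1 by 0.43 (SE 0.24, adjusted p = 0.536) and Prlr by 0.61 (SE 0.29, adjusted p = 0.412). All of these had higher means in ML. In a fit of only the groups compared, Esr1, Prlr and Areg passed the threshold (adjusted p = 0.023, 0.0409 and 0.0466).

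Other groups fell from HR-positive LP to ML in part of their members. Of 19 lineage transcription factors 8 fell by either adjustment (camera adjusted p = 2.92e-06, and adjusted p = 0.029 with an estimated correlation), with Cebpb down from 613 ± 122 to 85.2 ± 19.6 CPM and Runx2 from 21.3 ± 1.29 to 0.808 ± 0.838 CPM. Of 21 Wnt genes 10 fell by either adjustment (camera adjusted p = 0.000174, and adjusted p = 0.046 with an estimated correlation), among them Wnt5b, from 84.9 ± 13.5 to 1.44 ± 1.05 CPM, and the R-spondin receptor gene Lgr6, from 64.6 ± 3.23 to 0.632 ± 0.609 CPM. Innate defence genes fell in 6 of 12 (7 adjusted over the list alone, camera adjusted p = 1.07e-07, and adjusted p = 0.046 with an estimated correlation), with the lactoferrin gene Ltf down from 1459 ± 190 to 21.8 ± 13.0 CPM. Notch genes fell in 7 of 16 (8 adjusted over the list alone, camera adjusted p = 0.0051, and adjusted p = 0.0953 with an estimated correlation), with Notch1 at 86.8 ± 11.5 CPM in ML. Egfr fell from 50.2 ± 4.34 to 1.22 ± 0.0498 CPM and was 1 of 3 EGF family genes of 9 that fell by either adjustment (camera adjusted p = 0.375). Immediate early and heat shock genes fell in 7 of 19 (10 adjusted over the list alone, camera adjusted p = 2.55e-09, and adjusted p = 0.139 with an estimated correlation), with Egr1 down from 2363 ± 440 to 925 ± 143 CPM. Inflammatory genes fell in 5 of 18 (6 adjusted over the list alone, camera adjusted p = 0.0347, and adjusted p = 0.63 with an estimated correlation), with Cxcl1 down from 117 ± 49.7 to 26.6 ± 6.60 CPM. The inflammatory call was lost without HR-positive LP replicate 2 or 3 or ML replicate 1 (adjusted p = 0.0811, 0.142 and 0.203) and with fry (0.214).

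Remaining lists showed few called members between ML and HR-positive LP. The camera test moved up oxidative phosphorylation (0 of 53 called, adjusted p = 0.0051, and adjusted p = 0.731 with an estimated correlation) and cell cycle genes (1 of 28 lower, Pcna, adjusted p = 0.0242, and adjusted p = 0.703 with an estimated correlation). Endothelial genes also moved up (0 of 10 called, camera adjusted p = 0.0242, adjusted p = 0.139 with an estimated correlation, and adjusted p = 0.0537 with the replicate block, which ends that call). Fibroblast genes had 1 of 10 lower and a median of 0.90 (camera adjusted p = 0.0396, and adjusted p = 0.547 with an estimated correlation). These counts were equal adjusted over the list alone, and at an unadjusted p below 0.05, by DESeq2 and by limma voom 0 oxidative phosphorylation and 0 endothelial genes were called. Leaving out HR-positive LP replicate 1 ended the calls of oxidative phosphorylation (adjusted p = 0.0597) and fibroblasts (0.0853), and leaving out replicate 2 those of endothelial (0.0678), fibroblast (0.095) and cell cycle genes (0.154). The cell cycle call was also lost without HR-positive LP replicate 3 (0.0622) and ML replicates 1 and 3 (0.181 and 0.165), and the fibroblast call without ML replicates 2 and 3 (0.149 and 0.0538). With fry, oxidative phosphorylation (adjusted p = 0.506), cell cycle (0.488) and fibroblast genes (0.202) were not called. Of 10 pan-luminal genes 1 fell (2 adjusted over the list alone, camera adjusted p = 0.168), the mucin gene Muc1, from 110 ± 12.3 to 17.7 ± 8.41 CPM, and the list was called without HR-positive LP replicate 1 (0.0243) or ML replicate 3 (0.0485). Of 14 basal genes 2 fell, of 7 immune genes 1 fell, and 0 of 4 erythrocyte, 0 of 3 adipocyte, 0 of 7 MHC class II and 0 of 23 repair genes were called by edgeR, by either adjustment, with camera adjusted p from 0.375 to 0.994. At an unadjusted p below 0.05 these were 1, 0, 0 and 1, and DESeq2 and limma voom called 0. Of 19 interferon genes 1 fell, Ifit2, from 5.11 ± 0.776 to 0.0471 ± 0.0816 CPM (3 higher and 2 lower adjusted over the list alone, camera adjusted p = 0.485). With the replicate block, edgeR also called the interferon genes Irf7 and Stat2 (adjusted p = 0.0426 and 0.0428) and the pan-luminal gene Epcam (0.0173). The interferon list had a median of 0.06 and a mean of -0.35, and MHC class II genes 0.01 and -0.22.

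In total 15 genes were higher and 1066 lower in ML than in HR-positive LP. The largest falls were -6.82 for Adamts15 (SE 0.47, adjusted p = 3.63e-06), a matrix protease gene, -6.80 for Lgr6, -6.32 for Paqr6, and -6.30 for Apod and Gpc6, followed by Trf, Btn1a1, Alpl, Kit and Igfbp5. Igfbp5, which encodes a binding protein of insulin-like growth factors, fell from 3512 ± 283 to 50.9 ± 24.8 CPM. Past a 2-fold rise stood Lars2 (1.41, SE 0.34, adjusted p = 0.0307), a mitochondrial leucyl-tRNA synthetase gene, and Upk3a (1.25, SE 0.32, adjusted p = 0.0383), a uroplakin gene. Lars2 was no longer called without HR-positive LP replicate 1 or 2 or ML replicate 2 (adjusted p from 0.101 to 0.142), and Upk3a without HR-positive LP replicate 1, 2 or 3 or ML replicate 1 or 3 (adjusted p from 0.0837 to 0.192). Il33, a cytokine gene, was among the 15 and rose from 34.0 ± 5.23 to 64.2 ± 9.88 CPM (log2 fold change 0.92, SE 0.17, adjusted p = 0.00532), and it was picked after its values were seen.

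The number of genes higher in ML than in HR-positive LP, such as Il33, Lars2 and Upk3a, depended on the fit. With the replicate number as a block 71 genes were higher and 1253 lower, and without the block 15 and 1066. Without HR-negative LP replicate 1 and 3 the number of higher genes was 63 and 36. It was 5, 4 and 5 without HR-positive LP replicate 1, 2 and 3, and 8, 6 and 8 without ML replicate 1, 2 and 3.

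ML and HR-negative LP, which differ in CD14 and by the sample labels in YFP, had the largest number of differing genes. Hormone sensing genes rose in 15 of 18, by either adjustment (camera adjusted p = 8.38e-10, and adjusted p = 0.164 with an estimated correlation), with Prlr up from 198 ± 95.1 to 6314 ± 1247 CPM and Areg to 1046 ± 148 CPM. Esr1 was higher by 3.43 on the log2 scale (SE 0.26, adjusted p = 1.4e-06) and Foxa1 by 3.12 (SE 0.26, adjusted p = 2.96e-06). The gate gene Pgr, not a member of that list, was higher by 5.51 (SE 0.45, adjusted p = 2.55e-06). Alveolar progenitor genes fell in 15 of 16 by either adjustment (camera adjusted p = 4.21e-10, and adjusted p = 0.029 with an estimated correlation), among them Kit, which fell by 7.69 (SE 0.55, adjusted p = 1.07e-06), and Elf5, which fell by 3.59 (SE 0.36, adjusted p = 1.14e-05). The gate gene Cd14 fell by 5.50 (SE 0.22, adjusted p = 3.02e-08). Milk synthesis genes fell in 8 of 10 by either adjustment (camera adjusted p = 2.76e-05, and adjusted p = 0.0953 with an estimated correlation), with Csn3 lower by a log2 fold change of -7.90 and Plin2 down from 293 ± 82.3 to 22.6 ± 5.10 CPM.

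Innate defence genes fell in 9 of 12 by either adjustment from HR-negative LP to ML (camera adjusted p = 0.000109, and adjusted p = 0.0953 with an estimated correlation), led by Lcn2, the lipocalin-2 gene, from 3969 ± 323 to 16.9 ± 12.5 CPM, and Ltf, from 4182 ± 427 to 21.8 ± 13.0 CPM. Lineage transcription factors fell in 10 of 19 and rose in 4 (12 and 4 adjusted over the list alone, camera adjusted p = 0.00235, and adjusted p = 0.0953 with an estimated correlation). Wnt genes fell in 12 of 21 and rose in 2 by either adjustment (camera adjusted p = 0.0147, and adjusted p = 0.111 with an estimated correlation), and Notch genes fell in 8 of 16 and rose in 2 (9 and 2 adjusted over the list alone, camera adjusted p = 0.0197, and adjusted p = 0.137 with an estimated correlation). Immediate early and heat shock genes fell in 12 of 19 and rose in 1 (13 and 1 adjusted over the list alone, camera adjusted p = 2.76e-05, and adjusted p = 0.299 with an estimated correlation). Oxidative phosphorylation genes rose in 24 of 53 and fell in 1 by either adjustment (camera adjusted p = 0.000424, and adjusted p = 0.703 with an estimated correlation). Transcripts of the mitochondrial genome held 1.56 ± 0.0781% of the counts in HR-negative LP, 2.10 ± 0.179% in HR-positive LP and 2.67 ± 0.230% in ML.

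Inflammatory genes fell in 9 of 18 and rose in 2 (10 and 3 adjusted over the list alone, camera adjusted p = 0.0771), with Cxcl2 down from 248 ± 144 to 2.73 ± 1.54 CPM, and the list was called without HR-negative LP replicate 1 (adjusted p = 0.0407) and with the filter of CPM over 1 (0.0318). Interferon genes split into 8 higher and 7 lower of 19 (9 and 8 adjusted over the list alone, camera adjusted p = 0.752), with Usp18 up from 1.51 ± 0.476 to 22.3 ± 2.45 CPM and Ifit2 down from 16.2 ± 2.93 CPM. The median of that list was 0.49 and the mean -0.14. Calls for MHC class II genes were 2 higher and 3 lower of 7 by either adjustment (camera adjusted p = 0.949), for EGF family genes 3 and 3 of 9 (4 and 3 adjusted over the list alone, camera adjusted p = 0.994), for cell cycle genes 4 and 1 of 28 (2 and 1 adjusted over the list alone, camera adjusted p = 0.907), and for repair genes 0 and 2 of 23 (0 and 1 adjusted over the list alone, camera adjusted p = 0.522). Pan-luminal genes gave 3 higher and 4 lower of 10, basal genes 1 and 6 of 14, immune genes 1 and 1 of 7, endothelial genes 2 and 0 of 10, adipocyte genes 0 and 2 of 3, and erythrocyte genes 2 and 0 of 4, by either adjustment. Fibroblast genes gave 2 higher and 4 lower of 10 (2 and 6 adjusted over the list alone). Camera adjusted p for these 7 lists lay between 0.192 and 0.907. Fry, which does not compare a list with other genes, called the basal (adjusted p = 0.00881), endothelial (0.0057), adipocyte (0.0487), erythrocyte (0.0323) and interferon lists (0.0283). The median and mean also differed in sign for EGF family genes (0.07 and -1.27) and immune genes (-0.30 and 0.52).

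**Figure D2:**
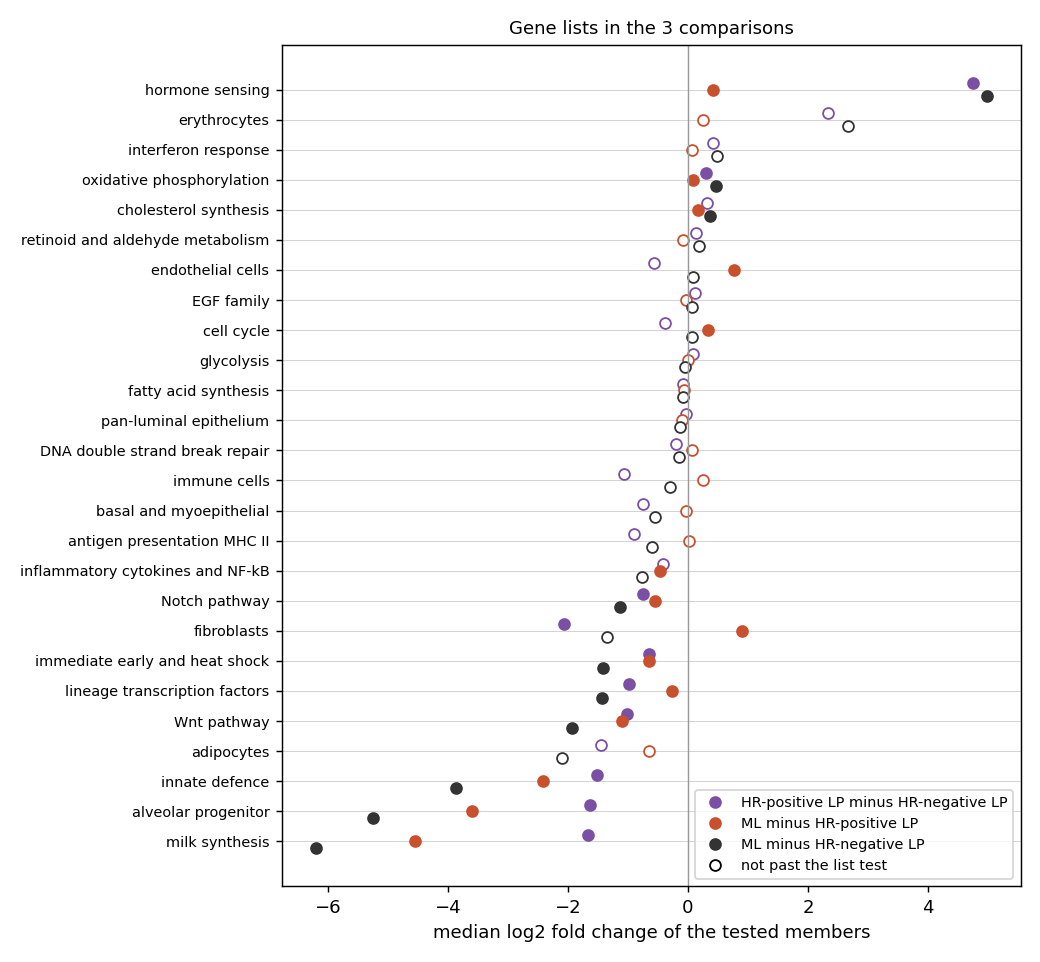
Median log2 fold change (x axis) of the tested members of 26 gene lists (y axis) in the 3 comparisons; filled circles mark lists with a camera adjusted p below 0.05 and open circles the others. Hormone sensing stands at 4.75 and 4.98 against HR-negative LP and at 0.41 between ML and HR-positive LP, while alveolar progenitor genes stand at -1.63, -3.60 and -5.25.

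Altogether 3700 genes were higher and 3389 lower in ML than in HR-negative LP, 2317 and 2202 of them by an absolute log2 fold change over 1. The largest rises were Gcnt4 (8.17, SE 0.64, adjusted p = 2.08e-06), Cdcp3 (7.09), Trpc6 (6.86), a calcium channel gene, Syt7 (6.79) and Krt78 (6.73), followed by Muc13, Itih2, Dpep2, Capn8 and Fer1l4. The largest falls were Paqr6 (-8.28, SE 0.38, adjusted p = 6.18e-08), Adamts15 (-8.27), Apod (-8.26), Lgr6 (-8.22) and Trf (-8.15), followed by Cck, Csn3, Lcn2, Gpc6 and Btn1a1.

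The profile of HR-positive LP lay between those of both other populations. With all 9 libraries fitted together, 0 genes were higher in HR-positive LP than in both others by edgeR (2 at an unadjusted p below 0.05), DESeq2 (1 unadjusted) or limma voom (5 unadjusted), and 1 was in edgeR fits of only the groups compared. Lars2 was the 1 gene lower than in both, at 548 ± 264 CPM in HR-negative LP, 247 ± 64.9 CPM in HR-positive LP and 658 ± 232 CPM in ML. At an unadjusted p below 0.05, 19 genes were lower, and DESeq2 and the fit with the replicate block called 5 each. Without HR-positive LP replicate 2 or ML replicate 2 the count was 0, and without HR-negative LP replicate 1 or 3 or HR-positive LP replicate 1 or 3 it was 2. Lars2 was not among the 2 without HR-positive LP replicate 1 (edgeR adjusted p = 0.13 between ML and HR-positive LP). Independent lists of these sizes would share 183 higher genes and 1.92 lower genes, and simulated data with no effect shared 0 in 5 simulations, in which 0 genes were called in any comparison, so that value was fixed. Of the 2731 genes higher in HR-positive LP than in HR-negative LP, 2703 were also higher in ML (635 for independent lists), and of the 2033 lower genes 1983 were also lower in ML (433 for independent lists). All 1066 genes lower in ML than in HR-positive LP were lower than in HR-negative LP too (227 for independent lists). Of the 15 genes higher in ML than in HR-positive LP, 14 were higher than in HR-negative LP (3.49 for independent lists). The simulated data, with 0 called genes, give no value for the overlap of comparisons that share libraries, and part of the excess may come from the libraries these comparisons share.

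On the log2 scale HR-positive LP lay at 0.698 ± 0.0285 of the way from HR-negative LP to ML (SD, n = 3), the median over 4519 genes. The 2317 genes higher in ML stood at 0.858 ± 0.0221 and the 2202 genes higher in HR-negative LP at 0.456 ± 0.0340. On the linear CPM scale these parts were 0.691 ± 0.0398 and 0.710 ± 0.0208. Genes lower in ML than in HR-negative LP by more than 64-fold (371 genes) had a median log2 fold change of -1.73 between HR-positive LP and HR-negative LP, and those lower by 16-fold to 64-fold (321 genes) one of -1.66. For genes lower by 2-fold to 4-fold (902 genes) it was -0.84. Genes higher in ML by more than 64-fold (452 genes) had a median of 7.12, leaving 0.62 between ML and HR-positive LP.

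**Figure D3:**
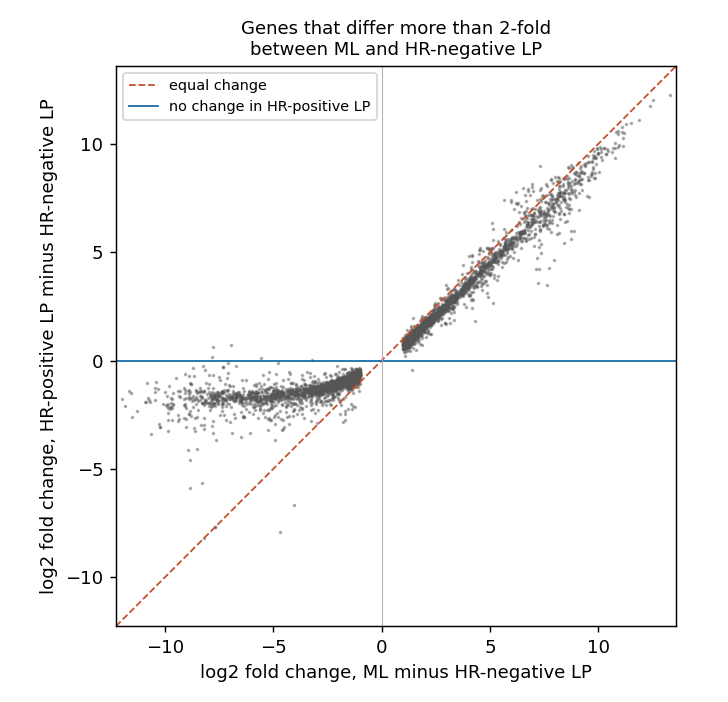
Log2 fold change of HR-positive LP (y axis) against that of ML (x axis), both over HR-negative LP, for the 4519 genes called between ML and HR-negative LP with an absolute log2 fold change over 1; each point is a gene, the dashed line marks equal change and the solid line no change in HR-positive LP. Genes higher in ML lie mostly a little below the dashed line, with a median gap of 0.28 for those 2-fold to 4-fold higher and 0.62 for those over 64-fold. Those lower in ML by more than 64-fold level off at a median of -1.73.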

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

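Scaling by library totals alone and thinning to the smallest library total were chosen after seeing the data, and all other alternatives before. No value with a test changed sign while called. Named genes were recomputed with the block, DESeq2, voom, DESeq2's size factors, no count filter, only the groups compared, and each library left out. Their 367 values gave 5326 recomputed values on the same side of the threshold, 110 that lost a call and 61 that gained one. List tests, recomputed with an estimated correlation, fry, the block, the filter of CPM over 1 and each library left out, gave 971, 55 and 27. For ML against HR-positive LP, the 15 higher genes became 71 with the replicate block, 88 with DESeq2, 50 with limma voom, 38 with upper quartile factors, 216 in a fit of only the groups compared, 30 with library totals alone and 2 with the fold change threshold, and ranged from 4 to 63 with a library left out. The 1 gene lower in HR-positive LP than in both others became 5 with the block, 5 with DESeq2 and 2 in the fit of only the groups compared, and ranged from 0 to 2 with a library left out. In the fit of only the groups compared 1 gene was higher than in both others. The cause was not tested. Genes lower in HR-positive LP than in HR-negative LP ranged from 1211 to 2290 with a library left out. Requiring an absolute log2 fold change over 1 left 1709 higher and 1016 lower genes for HR-positive LP against HR-negative LP, and 2317 and 2202 for ML against HR-negative LP. Of the 81 list tests, 34 passed with the preset correlation, 7 with an estimated correlation and 31 to 37 with a library left out. The 7 were alveolar progenitor genes in all 3 comparisons, and milk synthesis, lineage transcription factors, the Wnt pathway and innate defence in ML against HR-positive LP. Between ML and HR-positive LP, the replicate block ended the endothelial call and made calls of Epcam, Col1a2, Irf7, Stat2 and Slc2a1 among named genes, and it changed no other call of a named gene or list there. Against HR-negative LP, where same-numbered correlations were not all over 0.1, the block gave 3068 higher and 2395 lower genes in HR-positive LP and 4019 and 3590 in ML. Even so, 9 of 9 libraries correlated best with their own number, a count that is not independent of those correlations. That block ended the fibroblast call in HR-positive LP (adjusted p = 0.0593) and added inflammatory calls in both (0.038 and 0.0192). The position of HR-positive LP ranged from 0.674 to 0.724 with a library left out. Depth limited little, since thinning gave 2700 and 2068, 16 and 1058, and 3633 and 3358 genes higher and lower in the 3 comparisons.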

Other observations

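Thinning to 1 total, tests of the sequence of protein-coding Gapdh transcripts and of other splits, the medians by size of fold change, and the mixture fit with a replicate block were chosen after the results were seen, while the comparison with computed mixtures and the search over all Gapdh transcripts were set after the profiles but before their own values were seen. Genes of lipid metabolism went both ways between the populations. Of 15 fatty acid synthesis genes, 5 rose and 6 fell both in HR-positive LP and in ML against HR-negative LP, by either adjustment (camera adjusted p = 0.821 and 0.678), and 3 fell from HR-positive LP to ML (4 adjusted over the list alone, camera adjusted p = 0.195, and 0.0233 without ML replicate 2). The median and mean differed in sign in HR-positive LP (-0.08 and 0.20). The desaturase gene Fads2 went from 284 ± 37.2 CPM in HR-negative LP to 94.3 ± 10.4 CPM in HR-positive LP and 1.96 ± 1.24 CPM in ML, whereas Dgat2, a triglyceride synthesis gene, rose from 18.6 ± 7.08 to 386 ± 123 CPM in HR-positive LP. Among 21 cholesterol synthesis genes, 9 rose and 2 fell in HR-positive LP (10 and 3 adjusted over the list alone, camera adjusted p = 0.111, 0.0269 without HR-negative LP replicate 3 and 0.0293 with fry). In ML against HR-negative LP 10 rose and 3 fell by either adjustment (camera adjusted p = 0.0302, adjusted p = 0.63 with an estimated correlation, and 0.0529 and 0.0778 without HR-negative LP replicate 2 and ML replicate 2). From HR-positive LP to ML 1 fell by either adjustment, while the list moved up (camera adjusted p = 0.0182, adjusted p = 0.615 with an estimated correlation, and 0.103 and 0.301 without HR-positive LP replicate 1 and ML replicate 2 and 0.271 with fry).

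Glycolysis genes gave 6 higher and 7 lower of 19 in HR-positive LP against HR-negative LP (7 and 7 adjusted over the list alone), 7 and 9 in ML against HR-negative LP (8 and 9), and 0 and 3 in ML against HR-positive LP (0 and 4), with camera adjusted p of 0.907, 0.743 and 0.219 (the last 0.0102 without ML replicate 2). The aldolase gene Aldoc fell from 376 ± 65.0 to 138 ± 9.43 and 40.0 ± 5.0 CPM, while the pyruvate kinase gene Pkm rose from 451 ± 2.23 to 859 ± 91.1 CPM in HR-positive LP. Of 12 retinoid and aldehyde metabolism genes, 3 rose and 2 fell in HR-positive LP and 3 rose and 4 fell in ML against HR-negative LP, and 2 fell from HR-positive LP to ML, by either adjustment (camera adjusted p = 0.907, 0.907 and 0.375, the last 0.0227 with fry). Crabp2, a retinoic acid binding protein gene, stood at 61.4 ± 5.17, 18.0 ± 1.66 and 1.10 ± 0.446 CPM. The gate genes Cd14 and Pgr, also kept as a list, had 1 higher and 1 lower against HR-negative LP in both other populations and 1 lower in ML against HR-positive LP, by either adjustment. Camera adjusted p was 0.936 for HR-positive LP and 0.791 for ML against HR-negative LP. It was 0.094 for ML against HR-positive LP, 0.0441 and 0.0281 without HR-positive LP replicate 1 and ML replicate 2, and 0.000158 with fry, which also called the list in ML against HR-negative LP (0.000154). Camera gave the direction down for gate, glycolysis and retinoid genes in HR-positive LP, although their medians were 1.54, 0.09 and 0.14, and for gate and retinoid genes in ML against HR-negative LP, with medians of 0.01 and 0.18.

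HR-positive LP had 0 genes called higher and 1 called lower than in both other populations by edgeR (2 and 19 at an unadjusted p below 0.05, 0 and 5 by DESeq2, and 0 and 1 by limma voom). With all libraries thinned to 1 total, edgeR again called 0 and 1. A mixture of both other populations in one share is a candidate explanation: at an estimated 29.8% HR-negative LP, edgeR called 0 of 15306 genes between HR-positive LP and computed mixtures (241 at an unadjusted p below 0.05, where the same kind of fit of 2 groups called 1465 between ML and HR-positive LP), but the 241 lie under a share of 0.05 of the genes, and adjusted calls were 0 at 20%, 30% and 40%, 2 at 50%, and 549 higher and 33 lower at 10%, with 829, 278, 620, 1774 and 2103 unadjusted. Each computed mixture joined HR-negative LP and ML libraries of the same number. The block set it beside the HR-positive LP library of that number, although no source says that these libraries belong together. With the replicate block the mixture fit called 12 genes, against 2533, 754, 19, 307 and 1506 for mixtures with 10%, 20%, 30%, 40% and 50% HR-negative LP. The share was estimated from these libraries, and whether the gate held cells of both kinds, a sort carried cells or doublets over, or each cell carried both programmes in these proportions stays open, because sums of RNA do not show single cells.

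The share of HR-negative LP that the levels in HR-positive LP imply was 27.5 ± 3.23% for Cd14, 33.2 ± 3.12% for Kit, 28.8 ± 2.18% for Elf5, 25.9 ± 2.48% for Trf and 24.9 ± 2.07% for Csn3 (SD, n = 3). From genes higher in ML it was 36.7 ± 15.5% for Pgr, 26.8 ± 5.99% for Esr1, 29.2 ± 14.8% for Foxa1 and 35.7 ± 8.08% for Prlr. Over lists, the median was 28.7 ± 0.0996% for 15 alveolar progenitor genes, 29.0 ± 1.60% for 10 Notch genes, 29.7 ± 2.42% for 9 glycolysis genes, 38.5 ± 2.35% for 13 interferon genes and -10.9 ± 17.5% for 6 fibroblast genes. By library it was 29.7%, 27.3% and 32.3%. Genes that left the mixture with the block, named after their values were seen, were Col3a1 (-1.89, SE 0.28), Col1a2 (-1.85, SE 0.19), Rn7sk (-1.57), Col1a1 (-1.37), Lars2 (-1.34, SE 0.08), Upk3a (-0.72), Hp (0.39) and Dmbt1 (0.41), with 4 unnamed IDs between -1.33 and -0.78. Col3a1, Col1a2, Col1a1, Lars2, Rn7sk and the 4 unnamed IDs each had their lowest mean in HR-positive LP. Rn7sk stood at 7.53, 2.51 and 7.41 CPM in HR-negative LP, HR-positive LP and ML. Why these were low together was not tested.

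Gapdh, singled out like Pgk1 after its values were seen, was low beside other glycolysis genes, at 40.3 ± 3.49, 34.4 ± 3.94 and 24.9 ± 4.01 CPM, and Pgk1 was at 33.1 ± 2.25, 23.7 ± 1.85 and 23.7 ± 3.12 CPM. The median glycolysis gene stood at least 2.59 times above Gapdh in every library. CPM is not corrected for gene length, and how far length enters this ratio was not tested. Reads shared with copies of the gene may account for it: 58.4% of the 50-base windows of its protein-coding transcripts occur in another annotated gene, though 25.1% over all its transcripts left the matter open. Of the 223 genes that share a window with Gapdh, 215 are annotated as pseudogenes, and Pgk1 shares 53.9% of its windows. How reads with several matches were counted is not given in the sources used here, and no biological explanation was tested.

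The 3 libraries against 3 allow 10 splits, too few for a share under 0.05. The real split called 4764 genes between HR-positive LP and HR-negative LP, 1081 between ML and HR-positive LP and 7089 between ML and HR-negative LP. In each comparison 1 split, the real one, gave as many, and the highest of the others gave 0. Every other split mixes both populations, so differences between them enter its spread, and the 0 says little about chance. Lars2, the gene lower in HR-positive LP than in both others, stood at 376, 416 and 853 CPM in the HR-negative LP libraries, 177, 261 and 305 CPM in HR-positive LP and 502, 924 and 547 CPM in ML. Genes with 1 to 3 counts numbered 407, 778 and 489 in the HR-negative LP libraries and genes with 6 to 8 counts 382, 250 and 227, while HR-positive LP libraries had 491, 318 and 370 against 468, 320 and 404.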
